A study of Homo sapiens with 11 samples.

How the data were processed

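ZNF217 binding was measured by chromatin immunoprecipitation on tiling arrays in 3 human tumour cell lines: MCF-7 (breast carcinoma), Ntera2 (embryonal carcinoma) and SW480 (colon carcinoma), with 3 arrays per line, lettered A, B and C in the labels. A further pair of arrays came from Ntera2 cells, 1 after siRNA against ZNF217 and 1 after a control siRNA. The labels do not say whether the arrays of a line came from separate cultures, so every p-value measures the spread between these arrays. All arrays were a NimbleGen 50-mer design over the ENCODE pilot regions with coordinates in build hg17, per the file headers. Of the probes, 385149 were tiled over 44 regions and 3319 had random sequence.

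Each array gave a pair of files with the intensity of every probe, extracted with NimbleScan 2.3.19 or 2.3.22, per the file headers. The green scan holds Cy3 and the red scan holds Cy5. No background correction or normalisation is recorded for these intensities. The mismatch column was 0 throughout and was not used. The deposited value table holds the natural log of Cy5 over Cy3 intensity for each probe. Set against the scanner values it differed by at most 5.1e-15, which fixes its scale and direction. It was not centred, and its array medians ran from -0.237 for Ntera2 A to 0.311 for SW480 C. After centring it gave the same counts as the scanner files.

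The labels do not state which channel held the immunoprecipitated DNA. Cy5 likely held it, since it is channel 1, the deposited table puts Cy5 over Cy3, and the log ratios had a positive skew on all arrays except Ntera2 B (-0.12) and the knockdown array (-0.02). All signed values below are log2 Cy5 over Cy3 and rest on that reading. Over all probes, Ntera2 B correlated at -0.03 with both Ntera2 A and C, 0.06 with the control siRNA array and -0.31 with SW480 C. Over windows it correlated at -0.18 with Ntera2 A and -0.19 with Ntera2 C before loess, and at -0.59 and -0.52 after loess. It thus ran clearly against its replicates only after loess, and its direction is not settled. Ntera2 windows and the comparisons that rest on them are therefore given without Ntera2 B and with its sign turned, beside the result as labelled, in which every region had 0 Ntera2 windows called. The turned sign was chosen after seeing the data, and the array was never relabelled.

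Log2 ratios were computed from the intensities as given and centred on the median of each array, with no loess or quantile step. Probes were grouped into windows of 500 bp, windows with at least 5 probes were kept (34738), and the median of the probes was taken. The 9 arrays of the 3 lines were fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3, with the data.table package at version 1.17.8), and p-values were adjusted by Benjamini-Hochberg. All limma tests were two-sided. The lines shared 1 estimate of the spread per window, so an array of 1 line also moved the calls of the others. A window was called enriched at an adjusted p under 0.05 and a mean log2 ratio of at least 0.5. Windows equally far below 0 were counted as the opposite tail, a measure of the background. Called windows separated by at most 500 bp were merged into a site. Contrasts between lines used an adjusted p under 0.05, over all windows and also adjusted over the list of windows called in at least 1 line alone. On the 9 arrays that list held 855 windows called in MCF-7, 56 in SW480 and 0 in Ntera2, so the balance of directions within it is largely set by how it was chosen. In counts for a single region, the list alone instead means all kept windows of that region. The same limma fit was run on the mean of each tiled region and, for the input channel, on the mean log2 Cy3 intensity of each region.

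The knockdown and control arrays were compared as the median of knockdown minus control over the Ntera2 windows. The plan took the windows called from all 3 Ntera2 arrays. That fit called 0, so the windows called without Ntera2 B were used, and those called with its sign turned are given beside them. With 1 array per condition no p-value is given. The median was set against 10000 random lists of as many windows, matched on probe number in 4 bins and Cy3 brightness in 10 bins. The ZNF217 gene is not in a tiled region, so its own level could not be checked on the knockdown array.

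Sites named below follow a rule set before the data were examined. It takes the 10 sites of each line with the highest top window. For each contrast it takes the 10 sites with the largest difference in each direction whose arrays do not overlap. The planned fit, with all arrays as labelled, called 0 Ntera2 windows. After this was seen, the rule was also applied to the fit without Ntera2 B. The Ntera2 sites named by the rule, those higher in Ntera2 than in MCF-7, and those of SW480 against Ntera2 come from that fit. There the rule on overlap rests on 2 Ntera2 arrays. The 14 manually chosen ENCODE regions are covered, as are the 5 other regions with most called windows. The manual regions are named by their known gene content. The reference gene table is for another genome build, so no site was assigned to a gene and the planned share of windows near promoters was not computed.

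The file headers place the arrays in 3 scan batches. Batch 1 held MCF-7 A and B, batch 2 held MCF-7 C and the Ntera2 arrays A to C, and batch 3 held the SW480 arrays and both siRNA arrays. Scan batch was fitted as a block for MCF-7 against Ntera2. Other alternatives were normexp with an offset of 50, loess (span 0.3, 4 iterations), scaling of every array to a single median absolute deviation, the deposited value table, means in place of medians, 1000 bp windows, removal of the 10% of probes dimmest in Cy3, thresholds of 0.25 and 1, the replicate letter as a block, fits of only the line or pair compared, each array left out in turn, and runs of at least 6 consecutive probes above the 98th percentile on at least 2 arrays. Alternatives added after seeing the data were the turned sign, alone and with loess, the batch block without Ntera2 B, and SW480 against the control siRNA array of its own batch, for which the spread came from the other arrays.

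The windows fit was tested on simulated data with the spread of the 9 arrays and 200 windows shifted among 34738. At a shift of 0.75, it recovered 90% of shifted windows in MCF-7, 89.5% in Ntera2 and 86.5% in SW480. The shift was equal on all arrays of a line, whereas Ntera2 B ran against its replicates. The Ntera2 share therefore does not hold for the data as labelled, where the fit called 0 Ntera2 windows. For contrasts it recovered 61.5% between MCF-7 and Ntera2, 57% between SW480 and Ntera2, and 54.5% between MCF-7 and SW480 at a shift of 0.75, and 85%, 87% and 85% at a shift of 1. With the spread of the 8 arrays without Ntera2 B, 77% of the Ntera2 windows shifted by 0.75 were recovered, and 38.5%, 52% and 58.5% for the contrasts in the same order. For the regional fit, 8 of 44 regions were shifted by 0.2, and 50%, 75% and 50% were recovered for the same contrasts in that order. A knockdown shift of -0.3 put into 1410 windows was found as -0.3, below all of 1000 random lists. This outcome followed from how the shift was added. It tests neither the matching of the lists nor the spread between arrays. The median Cy3 intensity of the arrays ran from 1078.11 to 1735.22, and the small number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.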

Results

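Binding of the zinc-finger protein ZNF217, encoded by an oncogene on the long arm of chromosome 20, was profiled over 44 ENCODE regions in MCF-7, Ntera2 and SW480 cells, with 3 arrays per line. The study asked which genes ZNF217 regulates directly. A knockdown array and a control siRNA array from Ntera2 cells, 1 each, tested whether the signal depends on the protein. Median Cy3 intensity was 1293.78 to 1733 on the MCF-7 arrays, 1206.89 to 1400.78 on the Ntera2 arrays and 1078.11 to 1735.22 on the SW480 arrays. It was 1317.33 on the knockdown array and 1351.22 on the control array. The median Cy3 intensity of tiled probes over that of random probes ran from 1.11 on Ntera2 B to 2.729 on MCF-7 B. Log2 ratios of windows correlated between arrays of a line at 0.41 to 0.62 in MCF-7 and 0.32 to 0.49 in SW480. In Ntera2, these correlations ran from -0.19 to 0.73, and all those of Ntera2 B lay below 0.

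**Figure D1:**
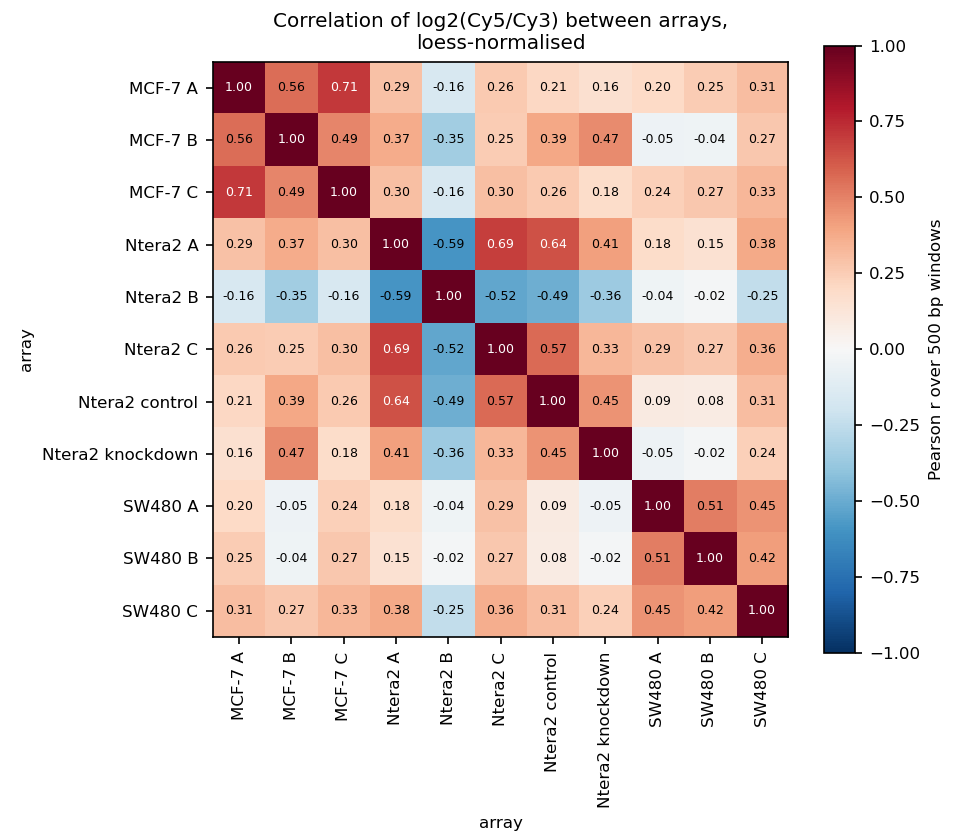
Pearson correlation of window log2 ratios (34738 windows, loess within each array) between all 11 arrays, each cell a pair of arrays. Ntera2 A and C correlated at 0.69, and Ntera2 B correlated with Ntera2 A at -0.59.

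To locate ZNF217 sites in breast carcinoma cells, MCF-7 windows were tested against 0. With limma on the 9 arrays, 855 windows (2.46%) were enriched and 27 lay in the opposite tail. They merged into 450 sites, of which 253 were a lone window, and 169 windows had a mean of at least 1. The count rested on the arrays MCF-7 A and B, since 289 windows were called without A and 374 without B. These arrays are the whole of scan batch 1, and with scan batch as a block 345 windows were called. Windows of 1000 bp gave 524. The highest site lay in the region with CFTR, MET and CAV1/CAV2 (ENm001, chromosome 7, 116358472 to 116358971), at 2.34 ± 0.3 (SD, n = 3, limma adjusted p 1.8e-07). At this window the Ntera2 arrays lay between 0.12 and 0.21 and the SW480 arrays between 0.3 and 0.7. It was followed by sites in ENr324 (chromosome X, 122662696, 2.3 ± 0.64), ENr221 (chromosome 5, 56095539, 2.3 ± 0.65) and ENr331 (chromosome 2, 220412511, 2.21 ± 0.69). The other sites among the top 10 had means from 1.86 to 2. They lay in ENr221 (56000539), ENr324 (122821696), ENr231 (chromosome 1, 148298634), ENm005 (chromosome 21, 34241611), ENr121 (chromosome 2, 118431988) and ENm001 (115588972). The largest adjusted p among the top 10 was 0.039, at the ENm005 site.

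In SW480, 56 windows in 39 sites were enriched and 7 lay in the opposite tail. Single arrays decided this count, which was 7 without SW480 A, 5 without SW480 C, 36 without MCF-7 A, 37 without Ntera2 C and 189 without Ntera2 B (70 in the opposite tail). Scaling every array to a single median absolute deviation gave 117 with 89 in the opposite tail, the line fitted alone 203 with 79, and normexp 107 with 2. Windows of 1000 bp gave 32. Of the windows called on the 9 arrays, the highest lay in Xq28 (ENm006, chromosome X, 153392372 to 153392871), at 1.54 ± 0.15 (SD, n = 3, limma adjusted p 0.00072). A window in ENr324 (122821696) stood higher, at 1.92 ± 0.25, and was called without Ntera2 B and with its sign turned, but not on the 9 arrays as labelled. The 5q31 cytokine cluster held the next (ENm002, chromosome 5, 131822264), at 1.4 ± 0.37, alongside a site in ENr331 (chromosome 2, 220389511) at 1.4 ± 0.28. The remaining top sites ran from 0.98 to 1.3 and lay in ENr132, ENr333, ENr133, ENr312, the beta globin region, ENm005 and ENr131.

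In Ntera2, limma on the 9 arrays called 0 windows. At an unadjusted p under 0.05, 410 windows passed the same threshold of the mean against 2 in the opposite tail. Runs of consecutive probes gave 191 sites present on at least 2 of the 3 arrays. Ntera2 B alone decided the limma count. Without it, 1410 windows (4.06%) in 768 sites were enriched and 18 lay in the opposite tail. With its sign turned, 792 windows in 458 sites were enriched and 15 lay in the opposite tail, and 789 windows were called in both fits. Both fits use arrays A and C, and the sign was turned because B ran against them, so this overlap is not independent support.

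The top Ntera2 sites without replicate B were also called with its sign turned, in 10 of 10 cases. Replicate B lay from -1.6 to -0.87 at these sites, so turning its sign largely set this outcome. The limma adjusted p of these sites with all arrays as labelled was 0.32 to 0.45. The highest lay in ENr324 (chromosome X, 122821696 to 122822195), at 2.24 ± 0.19 (SD, n = 2) without replicate B and 1.78 with its sign turned. A site in ENm005 (chromosome 21, 34241611) also had 2.24, and 1.9 with the sign turned. A site in ENm001 (chromosome 7, 116712972) had 2.23 and 1.96. The FOXP2 region (ENm012) held a site at 114459996 with 2.15 and 1.76, and ENr334 (chromosome 6) held a site at 41564433 with 2.12 and 1.95. In the HOXA region (ENm010, chromosome 7), sites lay at 26904761 (2.03 and 1.71) and 27013261 (1.89 and 1.63). The others lay in ENr211, ENm005 and ENr133, with means of 1.85 to 2. By rank with the sign turned, 8 of the top 10 were the same sites.

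To see where in the tiled regions ZNF217 windows gathered, called windows were counted per region. For these counts, over the list alone means that p-values were adjusted over all windows of the region in question. In Ntera2 the HOXA region stood first of the 44, with 158 of 638 windows (24.8%) without replicate B and 100 (15.7%) with its sign turned, and 159 without replicate B adjusted over the list alone. As labelled, every region had 0 Ntera2 windows. Over the list alone, the labelled fit called 1 in the HOXA region against 8 in the region of IGF2 and H19. All other regions together had 3.7% and 2% of their windows called. The widest Ntera2 site lay there too. Without replicate B it spanned 11 kb (26909761 to 26920760, 19 windows), and with the sign turned the widest spanned 6.5 kb (26948761 to 26955260). In the same region, 24 windows (3.8%) were called in MCF-7 and 4 (0.6%) in SW480, and over the list alone 24 and 8. Without replicate B the SW480 count there was 32, and 25 with the sign turned.

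**Figure D2:**
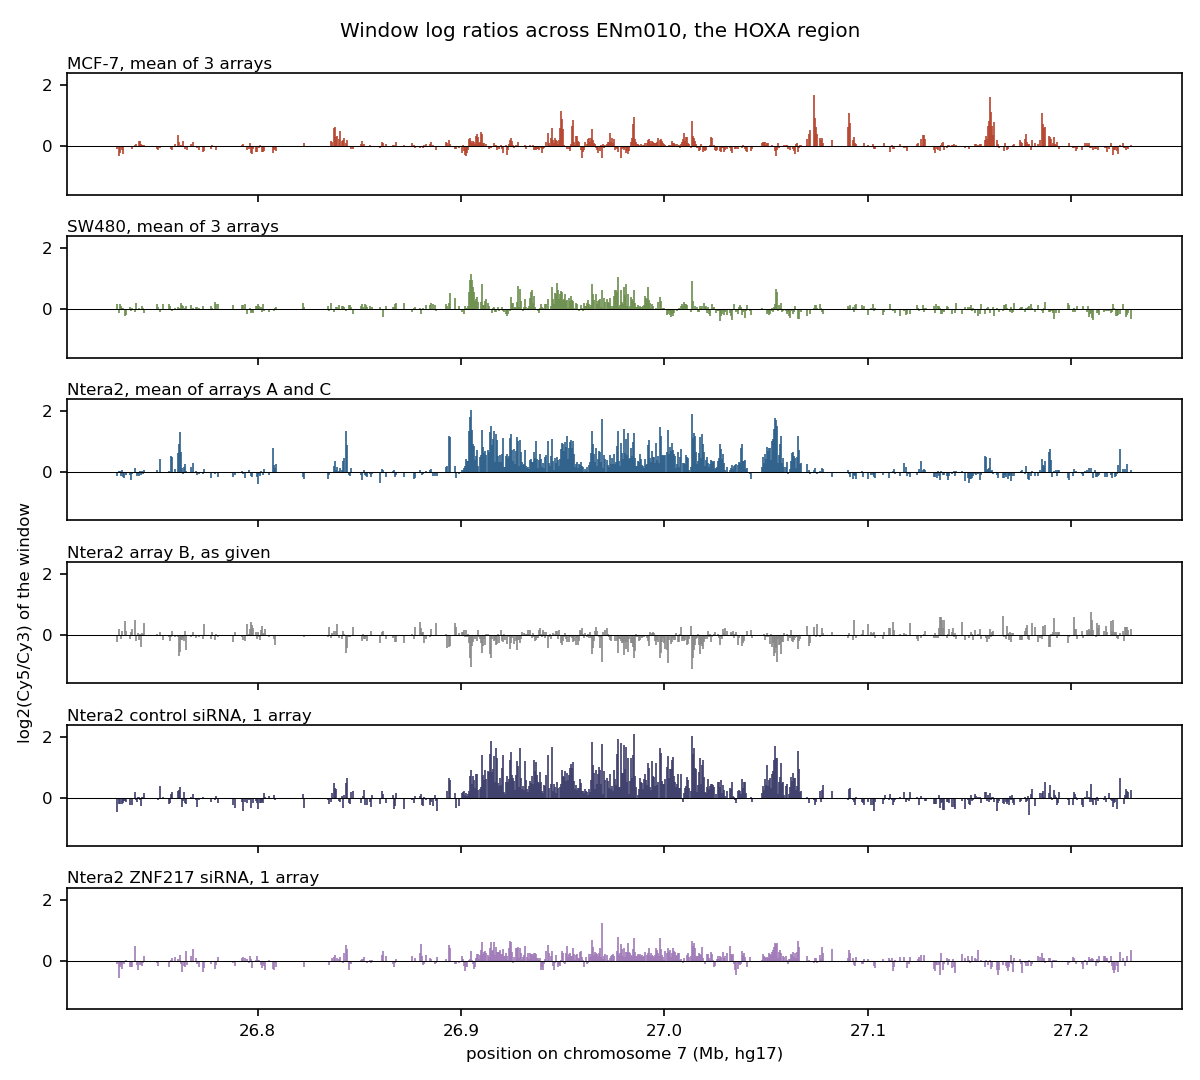
Window log2 ratio along the HOXA region (hg17, chromosome 7, position in Mb) as the mean of the MCF-7 arrays, of the SW480 arrays and of Ntera2 A and C, and for the Ntera2 B, control siRNA and knockdown arrays. Of the 638 windows, 158 were called in Ntera2 without replicate B, with medians of 0.83 on the control array and 0.26 on the knockdown array.

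ENm005 at 21q22 had 147 Ntera2 windows (7.6%) without replicate B and 89 (4.6%) turned, and 149 adjusted over the list alone. The region of IGF2 and H19 (ENm011) had 42 (5.1%) and 19 (2.3%), with 42 over the list alone. ENr334 had 11.7% and 6.1%, ENr331 10.2% and 4.9%, ENr231 10% and 6.9%, and ENr232 9.7% and 4.7%. In MCF-7, ENr231 on chromosome 1 had 71 (14.8%), ENr111 on chromosome 13 had 55 (9.9%) and ENr221 on chromosome 5 had 50 (8.2%). ENr212 had 26, as did ENr133. The widest MCF-7 site, 11 windows over 7.5 kb, lay in ENr111 (29575016 to 29582515). Among the manual regions, MCF-7 had most windows in ENm001 (83, with 84 over the list alone), then 22q12 (ENm004, 55, with 56) and ENm005 (43, with 38). Regions differ in size, and ENm001 is the largest, so counts do not rank them by share. The shares of these regions were 3.5%, 3.3% and 2.2%, against 3.8% in the HOXA region and 2.46% of all windows.

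Among the other manual regions, MCF-7 windows numbered 40 in the 5q31 cytokine cluster, 40 in Xq28, 22 in the region of LILR and KIR receptors, 21 in that of IGF2 and H19 and 15 in 7q21. The apolipoprotein and alpha globin clusters had 14 each, the beta globin region 7, 7q31-32 had 6 and the FOXP2 region 0. Adjusted over the list alone, these counts were 42, 40, 22, 19, 13, 14, 14, 6, 2 and 0 in the same order. In Ntera2 without replicate B, the manual regions not given above held from 14 windows in the beta globin region (10 turned) to 46 in Xq28 (29 turned). In SW480 on the 9 arrays, ENm005 had the most windows of any region (10), followed by ENr212 (8) and ENr312 (6). Their shares of windows were 0.5%, 1.3% and 0.8%, so by share ENr212 led. Over the list alone, ENm005 and ENr212 had 13 each and ENr312 had 9. Without Ntera2 B the HOXA region led in SW480, with 32 against 25 in ENm005, and with the sign turned with 25 against 21. The 5q31 cluster had 4 SW480 windows and the beta globin region 3 (6 and 3 over the list alone).

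**Figure D3:**
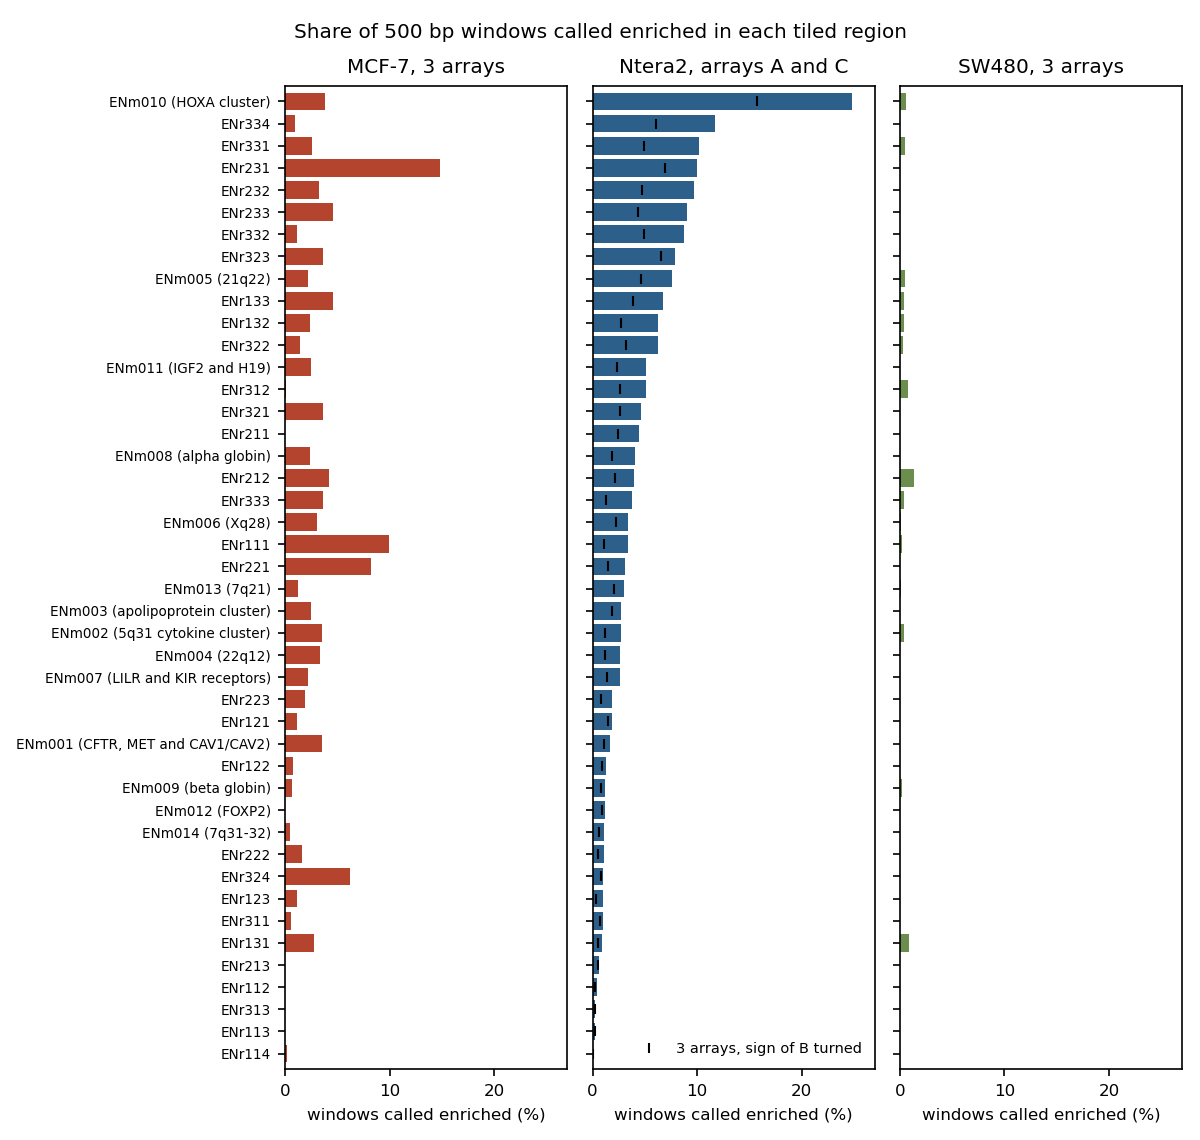
Percent of windows called enriched in each of the 44 tiled regions, as bars for MCF-7 and SW480 (9 arrays fitted) and for Ntera2 without replicate B, with ticks for Ntera2 with the sign of replicate B turned. The HOXA region leads in Ntera2 at 24.8% and 15.7%, and ENr231 leads in MCF-7 at 14.8%.

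Lines were next compared window by window. MCF-7 and Ntera2 differed at 117 windows with limma on the 9 arrays, 110 higher in MCF-7 and 7 higher in Ntera2. Adjusted over the list alone, 606 and 6 of 909 windows differed, but 855 of these were chosen as high in MCF-7 and 0 as high in Ntera2, which largely sets this balance. Without Ntera2 B, 281 were higher in MCF-7 and 765 in Ntera2, and with its sign turned 329 and 329. Leaving out other arrays gave 16 (Ntera2 C), 20 (SW480 C), 21 (MCF-7 A), 22 (MCF-7 B), 31 (Ntera2 A), 62 (SW480 B), 63 (SW480 A) and 439 (MCF-7 C). The count was 221 with normexp, 202 with loess, 332 with arrays scaled to a single median absolute deviation and 2 with the pair alone fitted. With scan batch as a block, 0 windows differed on all arrays, and 12 were higher in MCF-7 and 221 in Ntera2 without Ntera2 B. Within a batch the lines met only in batch 2, which held 1 MCF-7 array.

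The largest differences towards MCF-7 lay in ENm001 and ENr221. The ENm001 site at 116358472 had 2.18 as labelled (adjusted p 3.7e-05), 2.18 without Ntera2 B and 2.28 with its sign turned. The ENr221 site at 56095539 had 2.18, 2.26 and 2.37 in the same order. Next stood sites in ENr324 (122662696, 2.15, 1.99 and 2.04) and ENr331 (220412511, 2.01, 2.05 and 2.2). The top 10 also held sites in Xq28 (152907372, 1.87, 1.86 and 1.8), the 5q31 cluster (131742264, 1.72, 1.84 and 1.86), the region of IGF2 and H19 (1774220, 1.72, 1.79 and 1.72) and the HOXA region (27073261, 1.55, 1.61 and 1.72). With the pair alone fitted, 9 of the 10 sites named as labelled lost the call and the ENm001 site kept it (adjusted p 0.0023). With scan batch as a block, all 10 lost it, and the ENm001 difference was 1.85 (adjusted p 0.081). Towards Ntera2, no site met the rule with all arrays as labelled. Without Ntera2 B the largest lay in the FOXP2 region (114459996, -2.53, and -2.14 turned), ENr211 (25868928, -2.25 and -1.83) and the HOXA region (26969261, -2.16 and -1.88). In the HOXA region, 125 windows were higher in Ntera2 than in MCF-7 without replicate B and 55 with the sign turned. As labelled, 0 were higher in Ntera2 and 3 in MCF-7 there (3 and 10 adjusted over the windows of that region alone).

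MCF-7 and SW480 differed at 266 windows, 233 higher in MCF-7 and 33 higher in SW480, and at 696 and 51 of 909 adjusted over the list alone. The count was 24 without SW480 C, 56 without MCF-7 A, 78 without MCF-7 B, 97 without SW480 A, 110 without SW480 B, 160 without Ntera2 C, 613 without Ntera2 B and 662 without MCF-7 C. It was 558 with arrays scaled to a single median absolute deviation and 474 with the pair alone fitted. No scan batch held both lines, so line and batch cannot be told apart. The largest difference lay in ENr132 (chromosome 13, 112715065 to 112715564), where MCF-7 had 1.85 ± 0.5 and SW480 -0.43 ± 0.12 (SD, n = 3 each, limma adjusted p 0.00033). Further sites higher in MCF-7 lay in ENr221, ENr331, 22q12, Xq28, ENm001, the region of IGF2 and H19, ENr121 and the 5q31 cluster, with differences of 1.82 to 2.17. Higher in SW480 were sites in ENr312 (chromosome 11, 130894298, -1.38 for MCF-7 minus SW480, adjusted p 0.02), the beta globin region (5342186, -1.35, adjusted p 0.0088) and 8 others from -1.34 to -0.86.

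SW480 and Ntera2 differed at 1 window on the 9 arrays by limma, against 5922 at an unadjusted p under 0.05. It lay in ENr132 (112347565 to 112348064), at -1 in SW480 and 0.52 in Ntera2, was enriched in no line, and was named after its values were seen. Over the list alone, 28 windows were higher in SW480 and 8 in Ntera2. Without Ntera2 B, 61 were higher in SW480 and 1377 in Ntera2, and with its sign turned 34 and 357. The lone window still passed with the sign turned (-1.09, adjusted p 0.047). It was lost on leaving out any of MCF-7 A, MCF-7 B, Ntera2 A, Ntera2 C, SW480 A or SW480 C, and without SW480 B 2 windows differed. The count was 10 with normexp, 4 with loess, 6 with arrays scaled, 2 with means of probes and 0 with the pair alone fitted. No scan batch held both SW480 and any of Ntera2 A to C, so line and batch cannot be told apart here either. Against the control siRNA array of the same scan batch as SW480, 27 were higher in SW480 and 652 in Ntera2, but this sets 3 arrays against 1 that has no spread of its own. The largest difference without Ntera2 B lay in the region of IGF2 and H19 (1977220, -2.34 for SW480 minus Ntera2, and -2.23 turned). Without Ntera2 B the HOXA region held 108 windows higher in Ntera2 than in SW480, against 38 with the sign turned and 0 as labelled.

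At the level of whole regions, limma found 2 differing between MCF-7 and Ntera2 on the 9 arrays. ENr211 was lower in MCF-7 by -0.29 (adjusted p 0.014) and ENr221 higher by 0.17 (adjusted p 0.048). Without Ntera2 A, and with scan batch as a block, 0 regions differed, and 1 differed without MCF-7 A, Ntera2 C, SW480 A or SW480 B. No region differed between SW480 and Ntera2 or between MCF-7 and SW480, with 22 and 20 at an unadjusted p under 0.05. These counts moved to 18 and 18 with every array scaled to a single median absolute deviation, to 22 and 0 with the pair alone fitted, to 0 and 10 with normexp and to 0 and 4 with loess. Without MCF-7 B, 23 regions differed between SW480 and Ntera2, and without MCF-7 C, 20 differed between MCF-7 and SW480. Without Ntera2 B, the HOXA region was higher in Ntera2 than in MCF-7 (difference -0.22, limma adjusted p 0.026). ENr211 stayed called (-0.28, limma adjusted p 0.038), while ENr221 was no longer called. With scan batch as a block and without Ntera2 B, 0 regions differed between these lines. Without Ntera2 B and with no block, 7 regions were higher in Ntera2 than in SW480, among them the HOXA region (-0.21), the region of IGF2 and H19 (-0.25) and ENr332 (-0.31). With the sign turned, 0 regions differed for any pair, with 5, 7 and 15 at an unadjusted p under 0.05. Turning the sign also turned the trend of Ntera2 B with brightness. With loess applied before turning, regions did differ between MCF-7 and each of the other lines, with counts given in the closing sections.

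To find sites common to the lines, called windows were intersected. On the 9 arrays, 2 windows were called in both MCF-7 and SW480, where independent lists would share 1.4. They lay in ENm002 (131466264) and ENr132 (112575565), named after their values were seen. The number was 12 without MCF-7 C and 0 without MCF-7 A. It was 20 with normexp, 19 with arrays scaled and 62 with each line fitted alone. Leaving out Ntera2 B, an array of neither line, raised the overlap of MCF-7 and SW480 to 55, through the spread that the lines share. The 2 windows therefore do not show that MCF-7 and SW480 share few sites. Without Ntera2 B, MCF-7 and Ntera2 shared 303 windows where independent lists would share 41.1, and 13 in the opposite tail where 0.024 would be shared. They shared 202 with its sign turned (22.7 if independent) and 0 as labelled. SW480 and Ntera2 shared 95 without Ntera2 B (7.7 if independent) and 55 with its sign turned (3.4 if independent). MCF-7 and SW480 shared 55 (5.5 if independent) and 35 (4.3 if independent) in these fits. Without Ntera2 B, each of these 2 pairs shared 14 in the opposite tail, where 0.036 and 0.093 would be shared. As a ratio, the opposite tail exceeded independence by more than the enriched windows did, but as a number of windows by less. Short lists can reach higher ratios, and the opposite tails held only 46 windows in MCF-7, 18 in Ntera2 and 70 in SW480. Effects of probes common to all arrays can raise an overlap, so the excess alone does not show common ZNF217 sites. In all, 363 windows were called in at least 2 lines without Ntera2 B, and 45 in all 3 lines. With the sign turned these were 244 and 24.

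To ask whether the Ntera2 signal depended on ZNF217, the siRNA arrays were compared at windows chosen without them. Over the 1410 Ntera2 windows called without replicate B, the median log2 ratio was 0.6 on the control array and 0.25 on the knockdown array. The median difference was -0.34 (quartiles -0.52 and -0.17), and 1274 windows (90.4%) were lower on the knockdown array. Of 10000 matched random lists, 0 lay as low, with medians from -0.12 to -0.07. Over the 792 windows called with the sign turned, the median difference was -0.4, below all random lists (-0.13 to -0.06). These values describe 1 array of each kind and have no replicate check. The random lists were matched on probe number and Cy3 brightness, but not on signal or on how windows cluster into sites. The windows called in no line, 32534 (33071 turned), had a median of only -0.04 on the control array in both fits. Lists drawn mostly from such windows had little signal to lose. A weaker knockdown array would also put the called windows below them, so the lists do not show that the fall depends on ZNF217. Windows called only in MCF-7 or SW480 differed by -0.07 (-0.08 turned), and windows called in no line by 0 (-0.01 turned). The former had a median of only 0.13 on the control array (0.15 turned) and 0.06 on the knockdown array (0.07 turned). With so little signal to lose, their small difference does not show that the fall is particular to Ntera2 windows. At Ntera2 windows with a mean of at least 1, the difference was -0.51 (-0.56 turned).

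The difference is given by region below, and no test compared the regions. The HOXA windows went from a median of 0.83 on the control array to 0.26 on the knockdown array, with a median difference of -0.58 and 157 of 158 windows lower. With the sign turned the difference was -0.71, and 99 of 100 windows were lower. In the region of IGF2 and H19, 42 of 42 windows were lower, with a median difference of -0.6 (-0.64 turned). All 25 regions with at least 20 called windows had a negative median, from -0.6 to -0.03 in ENr211, as had all 16 with the sign turned (-0.71 to -0.28). At the top 10 Ntera2 sites, the ratio was lower on the knockdown array in 10 of 10 cases.

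**Figure D4:**
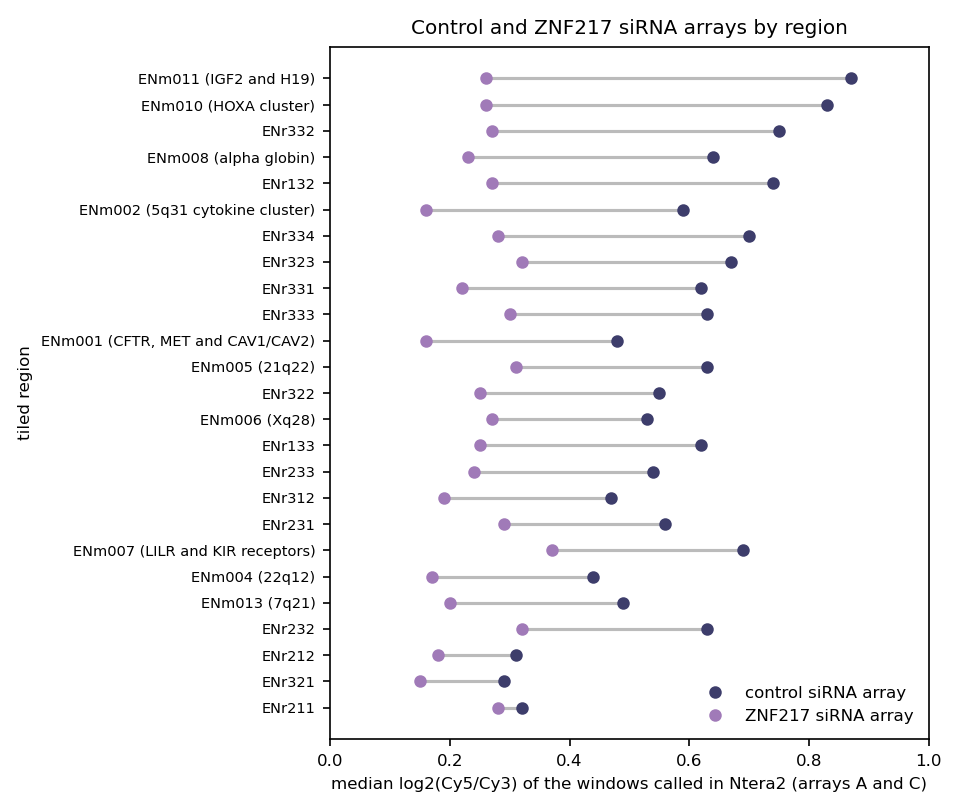
Median window log2 ratio on the control array and on the knockdown array (1 point each, joined by a line) at Ntera2 windows called without replicate B, for the 25 regions with at least 20 such windows. The knockdown point lies lower in every region drawn, from 0.87 against 0.26 in the region of IGF2 and H19 to 0.32 against 0.28 in ENr211.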

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

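The tests of the array Ntera2 B, of the knockdown and of the HOXA region were chosen after the results were seen. The counts over other splits of the arrays were planned before the splits were run.

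The lines differed in their window log2 ratios: 117 windows between MCF-7 and Ntera2, 1 between SW480 and Ntera2 and 266 between MCF-7 and SW480 passed limma's test of the difference. Each pair of lines has 10 splits of its 6 arrays, too few for a share under 0.05. For the windows, 1 split of 10, the real one, gave as many calls in each pair, and the highest of the other splits was 0. Between MCF-7 and Ntera2, 2 regions differed, and 2 of 10 splits gave as many. The highest other split gave 3 and set MCF-7 A, MCF-7 C and Ntera2 B against the rest, which follows no scan batch. With scan batch as a block, 0 windows and 0 regions differed between MCF-7 and Ntera2. For regions of the other pairs the real value and the highest other were both 0, so 10 of 10 splits gave as many.

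The input channel (Cy3), which the comparisons of binding do not use on its own, also differed between MCF-7 and the other lines. Its regional mean differed in 8 regions between MCF-7 and Ntera2 and in 11 between MCF-7 and SW480, and in 0 between SW480 and Ntera2 (7 at an unadjusted p under 0.05). ENr231 on chromosome 1 was brighter in MCF-7 than in SW480 by 0.53 (limma adjusted p 0.00021), and ENr321 on chromosome 8 by 0.44 (adjusted p 0.00082) and brighter than in Ntera2 by 0.34. ENr132 was dimmer in MCF-7 than in SW480 (-0.48) and in Ntera2 (-0.45), as was ENm011 (-0.48 and -0.33). ENr211, the region with lower ratios in MCF-7 than in Ntera2, was brighter in MCF-7 than in SW480 by 0.43, while its difference from Ntera2 (0.24, adjusted p 0.078) missed the threshold. Copy number and the batch of hybridisation would both move this channel, and no test here separates them.

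The Ntera2 B array ran against the other Ntera2 arrays, weakly over windows before loess (-0.18 with A, -0.19 with C) and strongly after it. The medians at strong sites and the correlations that follow are after loess. An array with little signal would sit near 0 at strong sites, but its median was -0.71 at the 200 windows highest on the control siRNA array, where Ntera2 A had 1.02 and Ntera2 C 0.9. DNA of another line would give a positive correlation with that line, but the highest correlation of Ntera2 B with an MCF-7 or SW480 array was -0.02. An exchange of dyes or of files stays open. The correlation of -0.59 with Ntera2 A is the pattern itself and decides nothing. Swapped files alone would also turn the trend with brightness. The median log2 ratio went from -0.18 at the dimmest to 0.32 at the brightest probes on Ntera2 B, as on Ntera2 A (-0.12 to 0.21) and C (-0.11 to 0.2). Its deposited median of -0.127 also had the sign of those of A (-0.237) and C (-0.141). These values go against swapped files but do not settle it, since MCF-7 C of the same batch had the opposite trend (0.12 to -0.14) and a median of 0.076. No biological explanation was tested, since the array carries the same label as its replicates.

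Log2 ratios at Ntera2 windows were lower on the knockdown than on the control array. A trend with probe brightness is not the whole cause, since after loess the median difference was -0.22, below the random lists (-0.03 to 0.02), and -0.27 with the sign of Ntera2 B turned (-0.04 to 0.03). Loss of ZNF217 and a weaker precipitation on the whole knockdown array cannot be told apart with 1 array of each. The knockdown median was 42.6% of the control median over all called windows, 31.5% in the HOXA region and 44.2% outside it, and with the sign of Ntera2 B turned 42.9%, 34.4% and 44.4%. Both explanations would lower all windows, and the ZNF217 gene is not tiled. The partial loss is consistent with an siRNA that leaves some protein, which remains untested.

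The HOXA region held many Ntera2 windows without replicate B or with its sign turned, and 0 as labelled. A trend with brightness would fade after loess, but 18.7% of its windows were still called without replicate B, against 2.3% elsewhere, and 14.4% with the sign turned. Low input in Ntera2 would raise the ratio, but input there was lower in MCF-7 than in Ntera2, by -0.23. The region ranked first of the 44 under median centring and loess, each without replicate B and with its sign turned. All of these fits use Ntera2 A and C, so the ranks are not independent of each other. As labelled there was no rank, since every region had 0. Dense occupancy of HOXA by ZNF217 in embryonal carcinoma cells may explain the pattern, as a hypothesis found and tested on the same arrays. The lower signal there on the knockdown array goes the same way, with the same open question about the precipitation.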

How the results depend on the processing

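All alternatives were set before the data were examined except the turned sign of Ntera2 B, the batch block without Ntera2 B, and SW480 against the control siRNA array. The balance of directions turned in some counts. MCF-7 against Ntera2 had 110 windows higher in MCF-7 and 7 in Ntera2 as labelled, but 281 and 765 without Ntera2 B and 12 and 221 with the batch block without it. SW480 against Ntera2 had 0 and 1 as labelled, but 10 and 0 with normexp and 4 and 0 with loess. The median knockdown difference stayed negative under every alternative, at -0.216 with arrays scaled to a single median absolute deviation. It moved by more than 0.143, the spread between the medians of Ntera2 A and C, only at a threshold of 1 (-0.51). That spread is between 2 arrays of the line, on which the windows were chosen. It does not measure how a knockdown difference would vary, since there is 1 array of each kind. The deposited value table gave the same counts and the same knockdown difference. The cause of the changes below was not tested, except that stricter thresholds, wider windows and fewer arrays leave fewer windows or samples by construction.

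As labelled, 855 windows were enriched in MCF-7, 0 in Ntera2 and 56 in SW480, 2 were shared between lines, 117 differed between MCF-7 and Ntera2, 1 between SW480 and Ntera2 and 266 between MCF-7 and SW480, and 2, 0 and 0 regions differed. Normexp gave 107 windows in SW480, 20 shared, 221 (220 higher in MCF-7) and 10 differing from Ntera2, and 10 regions between MCF-7 and SW480. Loess gave 1 shared, 202 and 4 differing from Ntera2, and 4 regions between MCF-7 and SW480. Scaling to a single median absolute deviation gave 117 in SW480 (89 in the opposite tail), 19 shared, 332 (296 higher in MCF-7), 6 and 558 (466 higher in MCF-7) differing, and 18 regions for SW480 against Ntera2 as against MCF-7. Means of probes gave 5 shared and 2 for SW480 against Ntera2. Windows of 1000 bp gave 524 in MCF-7, 32 in SW480 and 1 shared. Without the dimmest probes 1 region differed between MCF-7 and Ntera2. A threshold of 0.25 gave 6 shared, and a threshold of 1 gave 169 in MCF-7, 9 in SW480 and 0 shared. Fits of the line or pair alone gave 203 in SW480, 62 shared, 2, 0 and 474 differing, and 22 regions between SW480 and Ntera2.

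With the sign of Ntera2 B turned, 792 windows were called in Ntera2, 149 in SW480 and 244 shared, with 658, 391 and 425 differing and 0 regions between MCF-7 and Ntera2. With loess added these were 707, 210, 264, 1417, 668, 941 and 5, and 4 regions differed between MCF-7 and SW480. With scan batch as a block, MCF-7 had 345, and MCF-7 and Ntera2 differed at 0 windows and 0 regions, or 233 windows and 0 regions without Ntera2 B. SW480 against the control siRNA array, 1 array with no spread of its own, gave 679 windows (652 higher in Ntera2) and 7 regions. Runs of probes gave 199 sites in MCF-7, 191 in Ntera2 and 69 in SW480, against 450, 0 and 39.

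With the replicate letter as a block, 792 windows were called in MCF-7 and 65 in SW480, 1 was shared, 91, 0 and 250 differed, and 1, 14 and 11 regions differed. The letters do not pair the arrays. Deviations of arrays with the same letter correlated at -0.23 to 0.28, 3 of 9 above 0.1, and those with different letters at -0.3 to 0.29.

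Leaving out each array in turn gave 289 to 1198 windows in MCF-7, 0 to 1410 in Ntera2, 5 to 189 in SW480 and 0 to 363 shared. The pairs differed at 16 to 1046 (MCF-7 and Ntera2), 0 to 1438 (SW480 and Ntera2) and 24 to 662 windows (MCF-7 and SW480), and at 0 to 3, 0 to 23 and 0 to 20 regions. The knockdown difference ran from -0.45 to -0.341, with 472 Ntera2 windows when Ntera2 A was left out as well as B. Ntera2 B alone decided whether windows were called in Ntera2 (1410 without it). MCF-7 A (289 without it) and MCF-7 B (374) carried the MCF-7 count, and SW480 A (7) and SW480 C (5) the SW480 count. Shared windows numbered 12 without MCF-7 C and 363 without Ntera2 B. The 23 regions between SW480 and Ntera2 came without MCF-7 B, 7 without Ntera2 B, and the 20 between MCF-7 and SW480 without MCF-7 C. Named sites kept their direction in every fit run on them. Cases fixed by construction were not counted: the deposited table, the lower threshold, and leaving out Ntera2 B for sites named without it. On leaving out an array, sites stayed past the threshold in 79 cases and lost it in 11 for MCF-7, 71 and 19 for SW480, 80 and 0 for Ntera2, 239 and 11 for MCF-7 and Ntera2, 143 and 37 for MCF-7 and SW480, and 142 and 18 for SW480 and Ntera2. With the other settings these were 107 and 3, 106 and 4, 108 and 2, 289 and 11 (9 of them with the pair alone fitted), 189 and 11, and 195 and 5. With scan batch as a block they were 7 and 3 for MCF-7, and all 10 sites of MCF-7 and Ntera2 named as labelled lost the call, while 17 of the 20 named without Ntera2 B kept it in the block without that array. Against the lone control siRNA array, 16 of 20 sites of SW480 and Ntera2 kept it. A lone or reduced group is assumed to vary like the others. Signal over background limits Ntera2 B most, with Cy3 at 1.11 times the random probes.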

Other observations

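The division of the HOXA region described here was drawn after its values were seen. The longest chain of Ntera2 windows called without replicate B, with at most 10 kb between windows, spanned 144.5 kb of chromosome 7 (26893761 to 27038260) and held 126 called windows. With the sign of replicate B turned, 81 windows in this span were called. The mean log2 ratio over its 277 windows was 0.58 on Ntera2 A, 0.51 on Ntera2 C and -0.14 on Ntera2 B. It was 0.61 on the control siRNA array and 0.17 on the knockdown array. SW480 had 0.15 ± 0.05 (SD, n = 3) and MCF-7 0.06 ± 0.06. In the rest of the region, 361 windows, the means of all arrays lay between -0.02 and 0.08. Single windows were called there too, 32 in Ntera2 without replicate B and 19 with its sign turned. In the fit without Ntera2 B, 19 were called there in MCF-7 and 2 in SW480. An Ntera2 site of 14 windows (27049261 to 27057760, without replicate B) also lay outside the span.

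Within that span, SW480 had its own chain of windows called without Ntera2 B, over 28 kb (26964261 to 26992260) with 11 called. On the 9 arrays, 4 SW480 windows were called in the whole region. There the mean was 0.31 ± 0.06 in SW480, 0.04 ± 0.06 in MCF-7, 0.56 ± 0.06 on Ntera2 A and C, 0.78 on the control array and 0.25 on the knockdown array. In the rest of the Ntera2 span, 221 windows, SW480 had 19 windows called without Ntera2 B and a mean of 0.11 ± 0.05.

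Of the 45 windows called in all 3 lines without Ntera2 B, in 40 sites and 19 regions, 44 were lower on the knockdown than on the control array, and 43 were below 0 on Ntera2 B. With the sign of Ntera2 B turned, 24 of them were called in all lines. The highest, in ENr324 (chromosome X, 122821696 to 122822195), had 2 ± 0.43 in MCF-7, 1.92 ± 0.25 in SW480 and 2.24 ± 0.19 on Ntera2 A and C. It was 1.96 on the control array and 1.27 on the knockdown array. In ENr321 (chromosome 8, 119192221), the values were 1.61, 1.32 and 1.83 in the same order of lines, with 1.83 on the control array and 0.58 on the knockdown array.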
